A study of Mus musculus with 9 samples.

How the data were processed

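RNA of the aorta from 9 male mice was hybridised to Affymetrix mouse expression arrays, 1 array per sample. The labels give 5 BMAL+/+ and 4 BMAL-/- samples as biological replicates. The strain and title of array F01 say BMAL+/+ and its source name says BMAL-/-. It was kept in BMAL+/+, which also gives the group sizes in the series' design text, and was moved to BMAL-/- as an alternative. The groups share no replicate numbers, so no pairing was possible.

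The deposited table holds log2 expression values for 45101 probe sets. The submitters' processing notes name GCRMA and MAS5 without a role or a version. GCRMA corrects background from probe sequence, normalizes across arrays and summarises probes on a log2 scale, whereas MAS5 gives linear signals. The deposited log2 values have a dense floor between about 2 and 3 and no detection flags. Which background, normalization and summary settings were used is not given in the sources used here. A floor of this kind compresses the spread of transcripts near background, so that very small shifts there can look precise. The values were used as deposited, without a further normalization or a filter on dim probe sets. Array medians lay between 3.13 and 3.24. The number of arrays limits the precision.

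The 64 control probe sets were left out, which left 45037. The platform annotation pairs 34945 of them with 1 gene, 932 with several and does not list 9160. No gene was named from a probe set with several genes. Symbols were updated through gene identifiers to RefSeq names of assembly GRCm38.p6, which held 34741 of the single-gene probe sets. Each of the 18194 genes was represented by its brightest probe set. The build behind the array is not given in the sources used here, so no coordinates are printed.

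The test was fixed before the data were examined. A linear model with genotype as its only term was fitted to each probe set with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, which had 1.76 prior degrees of freedom), and p-values were adjusted by Benjamini-Hochberg over all 45037 probe sets, two-sided, with a threshold of 0.05. Differences are BMAL-/- minus BMAL+/+ on the log2 scale, with limma's standard error (SE). For Arntl, a two-sided exact permutation test over all splits of the 9 arrays was added, for which the smallest possible p is 0.00794. The same test was also run on the mean of each list per array, with and without F04 and F05. That use was not among the tests fixed beforehand. A total of 31 gene lists, also fixed before the data were examined, were tested with camera, which asks whether a list's genes differ from all other genes, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. Lists needed at least 5 measured genes. Of 474 list genes, 48 had no probe set paired with that gene alone.

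Genes were named by a rule fixed before the data were examined. It takes Arntl, the genes with the largest change among those past the threshold whose groups do not overlap (up to 12 per direction, filled to 5 by the smallest p and then said not to pass), every member of both clock lists, the 4 members with the smallest p of each other list that was called or held a passing gene, and 9 markers of tissue composition.

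The alternatives were quantile normalization of the deposited values, centring of the arrays on 1 median, eBayes without a trend and with a robust trend, array weights, filters at the median and the upper quartile of brightness, the one-way ANOVA named in the design text, removal of probe sets that can match several genes, a floor at each array's 20th percentile, a minimum fold of 1.5, F01 in BMAL-/-, and the removal of each array in turn. For lists they were an estimated correlation, fry, the mean of a gene's probe sets and genes above the median brightness. Camera has no robust option, so that alternative was not run for lists. A comparison without the arrays F04 and F05 was added after their clock gene values were seen. It holds 4 BMAL+/+ and 3 BMAL-/- arrays.

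The scripts were tested on simulated data with the means of the real probe sets and the residual spread of the 7 other arrays. Of 45037 probe sets, 200 were changed, all above the median brightness. Noise was drawn independently, without the discordance of F04 and F05, the correlation between genes or the shift of dim probe sets. The shares below are therefore not the power of the real comparisons. For 9 arrays, 16% of the 1.5-fold, 32% of the 2-fold, 66% of the 4-fold and 78% of the 8-fold changes were recovered. Without F04 and F05 these shares were 6%, 14%, 52% and 82%. Plots were drawn with matplotlib 3.10.9.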

Results

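Transcript levels were measured in the aorta of male mice labelled BMAL+/+ or BMAL-/-, that is, with or without a working copy of Arntl, the gene of BMAL1, a transcription factor that drives the positive arm of the circadian clock. There were 5 arrays from BMAL+/+ mice (F01, F04, F07, F09 and F10) and 4 from BMAL-/- mice (F02, F03, F05 and F08). The mice had at least 2 weeks in cycles with 12 h of light, then at least 30 h of darkness, and tissue was taken at ZT14. The labels speak both of the thoracic aorta and of a dissection that reached past the femoral branches. The deposited values were log2 expression with array medians from 3.13 to 3.24. The comparison asks which aortic transcripts differ between mice with and without BMAL1 at this time of day.

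The targeted gene, Arntl, was looked at first. On its brighter probe set the arrays labelled BMAL+/+ F01, F07, F09 and F10 read between 2.74 and 2.82, and those labelled BMAL-/- F02, F03 and F08 read between 5.87 and 6.22. The array labelled BMAL+/+ F04 read 6.67, above every BMAL-/- array, and the array labelled BMAL-/- F05 read 2.77, within the range of the other BMAL+/+ arrays. Over the groups as labelled the level was 3.55 ± 1.74 (SD, n = 5) in BMAL+/+ and 5.23 ± 1.64 (SD, n = 4) in BMAL-/-, a difference of 1.67 ± 1.02 (SE), with an exact permutation p of 0.19 and an adjusted p of 0.386. The second probe set read 2.31 ± 1.02 (SD, n = 5) and 3.24 ± 1.42 (SD, n = 4), with an exact permutation p of 0.198. On it F04 read 4.14, F03 4.76 and F08 4.13, whereas F02, labelled BMAL-/-, read 2.18, near the 1.81 to 1.88 of F01, F05, F07, F09 and F10. On the brighter probe set Arntl was higher on F02, F03 and F08, labelled BMAL-/-, than on F01, F07, F09 and F10, labelled BMAL+/+, the reverse of a loss of its transcript. On the second this held for F03 and F08, with F02 near the floor. Whether either probe set lies in the deleted part of the gene is not given in the sources used here, and a probe set outside it does not check the labels. F01, whose labels disagree, lay with the BMAL+/+ arrays.

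The same 2 arrays stood with the other genotype at other clock genes. Npas2, a partner of BMAL1, read 8.36 on the array labelled BMAL+/+ F04 and between 3.37 and 3.40 on the other BMAL+/+ arrays, and it read 3.40 on the array labelled BMAL-/- F05 and between 7.90 and 8.52 on the other BMAL-/- arrays. Nr1d2, a clock repressor of the REV-ERB family, read 5.81 on F04 and 11.2 on F05, against 10.4 to 11.7 on the other BMAL+/+ arrays and 5.08 to 5.89 on the other BMAL-/- arrays. All directions below rest on the labels, and each is given for the 9 arrays as labelled and, where it is stated, for the 7 arrays without F04 and F05.

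**Figure D1:**
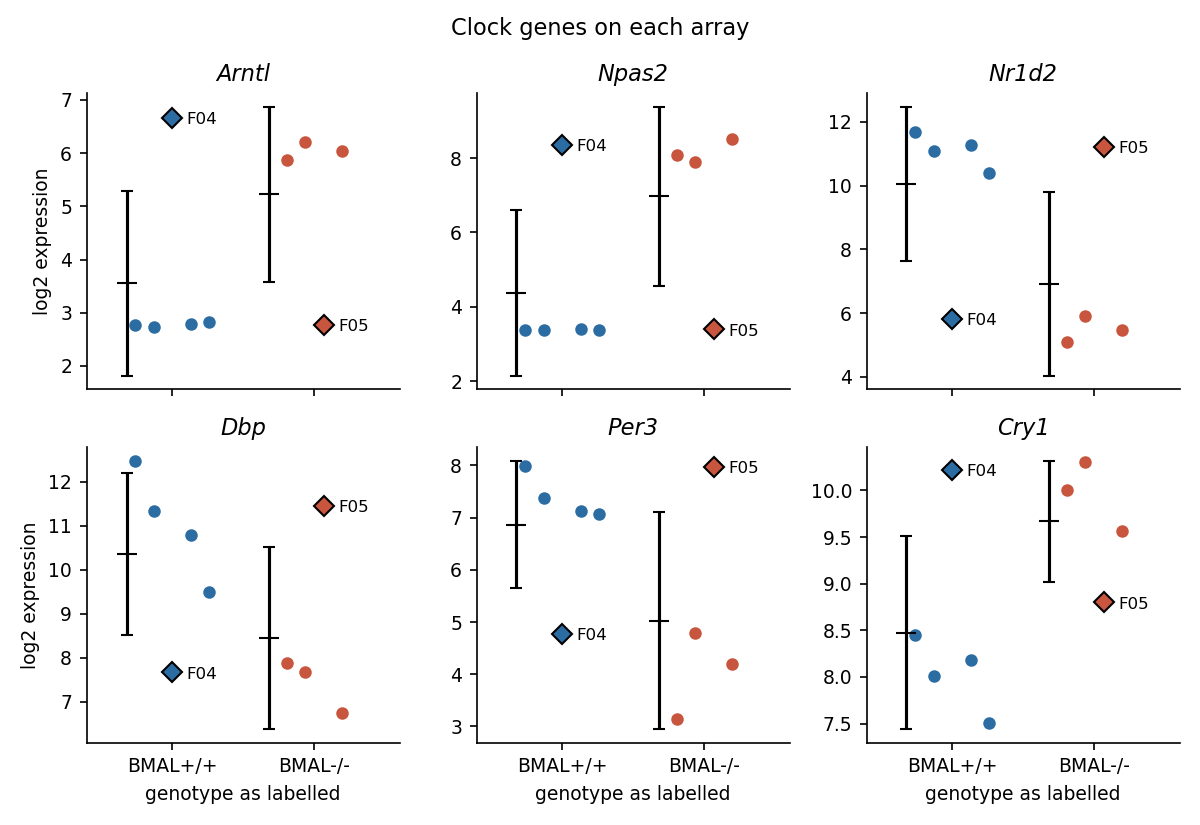
Log2 expression of 6 clock genes (vertical axes) on the 9 arrays, by genotype as labelled (horizontal axis). Points are arrays, diamonds mark F04 and F05, and bars are the group mean with SD. At Arntl the array labelled BMAL+/+ F04 reads 6.67 and the array labelled BMAL-/- F05 reads 2.77, each with the other group.

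With the 9 arrays as labelled, no probe set passed the threshold. In limma, 0 of 45037 probe sets had an adjusted p under 0.05 and the smallest adjusted p was 0.37, and the F-test of the design text, run per probe set, also gave 0. At an unadjusted p under 0.05 there were 3903, of which 3565 were higher and 338 lower in BMAL-/-. Of the 3565, 3222 were below the median brightness, and above it 343 were higher and 322 lower. Quantile normalization changed the split to 1137 higher and 681 lower, and centring the arrays on 1 median changed it to 582 and 507. The count of 3903 went to 926 without F02, 1000 without F03, 1120 without F09, 1265 without F01, 1326 without F10, 1376 without F07, 10359 without F04 and 12949 without F08, to 851 (469 higher and 382 lower) with F01 in BMAL-/- and to 12339 with array weights. Without a variance trend the count was 2137. The groups did not overlap at 348 probe sets (0.773%), where chance gives 1.59%.

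The genes with the smallest p as labelled, none of which passed, were Enc1, Ccdc7a, Tekt1, Fignl1 and Fbxw14 among those higher in BMAL-/-, and C87436, Narf, Ccp110, Slf2 and Pias3 among those lower, each at an adjusted p of 0.37. Enc1, an actin-binding protein, read 8.21 ± 0.43 (SD, n = 5) in BMAL+/+ and 9.26 ± 0.29 (SD, n = 4) in BMAL-/-, a difference of 1.05. Narf had a difference of -0.89 and C87436 one of -0.86. Both other probe sets of C87436 had the opposite sign in the 7 arrays. Of the 5 higher genes, 4 lay near the floor in both groups, Fbxw14 and Fignl1 at 2.44 in BMAL+/+ and 2.52 and 2.54 in BMAL-/-, Ccdc7a at 3.03 and 3.23, and Tekt1 at 2.96 and 3.14. Narf read 3.17 in BMAL-/-, also near it.

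As a set, the 15 clock genes driven through E-boxes, the DNA element that BMAL1 binds, were lower in BMAL-/- as labelled. Their median difference was -0.71 and 13 of 15 were lower (camera adjusted p = 2.1e-05, adjusted p = 0.284 with an estimated correlation and 0.0718 with array weights). None passed over all genes or adjusted over the list alone. The differences were -3.13 ± 1.58 (SE) for Nr1d2, -1.91 for Dbp, -1.84 for Per3, -1.27 for Hlf and 1.19 for Cry1, each at an adjusted p from 0.37 to 0.387. The 7 measured genes of the positive arm, with those driven through the REV-ERB and ROR element, had a median difference of 0.13 and were not called (adjusted p = 0.549).

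Without F04 and F05, 4 probe sets passed, 3 of them clock genes. Npas2 rose from 3.38 ± 0.02 (SD, n = 4) in BMAL+/+ to 8.17 ± 0.32 (SD, n = 3) in BMAL-/- (adjusted p = 0.000511). Arntl rose from 2.78 ± 0.04 (SD, n = 4) to 6.05 ± 0.17 (SD, n = 3) (adjusted p = 0.000511). For both, the BMAL+/+ level lay near the floor, so no fold is given. Nr1d2 fell by 5.63 ± 0.34 (SE) on the log2 scale, from 11.11 ± 0.54 (SD, n = 4) to 5.48 ± 0.41 (SD, n = 3) (adjusted p = 0.0159). B3galt2, a galactosyltransferase, rose by 2.04 ± 0.14 (SE) on a probe set that is not its brightest (adjusted p = 0.0327), and it is named because so few passed. The 2 arrays were left out because of their clock genes, so these clock genes are not independent evidence of a difference. Nr1d2 no longer passed after quantile normalization, in that F-test, or without F01, F07, F10, F02 or F03, and B3galt2 did not pass after quantile normalization, in that F-test, or without F01, F07, F09, F10, F02 or F03. Arntl and Npas2 passed in each of these.

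Other E-box clock genes with a difference in the same direction as Nr1d2 were Dbp, at -3.59 ± 0.69 (SE), Per3 at -3.35 ± 0.42 (SE), Hlf at -2.36, Tef at -2.00 and Per2 at -1.60, with adjusted p of 0.18 to 0.208 over all genes. Adjusted over the list alone, 8 passed as lower (Nr1d2, Per3, Tef, Per2, Hlf, Dbp, Usp2 and Wee1) and 1 as higher, Cry1, a repressor of the clock (1.92 ± 0.28, SE). Bhlhe40 (-0.43), Cry2 (-0.40), Per1 (-0.11), Ciart (-0.22), Nr1d1 (-0.84) and Bhlhe41 (0.04) did not, of which Nr1d1, Ciart and Bhlhe41 had group means between 1.92 and 3.05 in the 7 arrays. The list's median was -0.93 (camera adjusted p = 3.9e-09, adjusted p = 0.164 with an estimated correlation). Of the positive arm, Npas2 and Clock (1.01 ± 0.16, SE) passed adjusted over the list alone, while Nfil3 (1.44), Rorb (0.18), Arntl2 (0.16), Rora (0.02) and E2f8 (-0.07) did not. This list was higher as a set (camera adjusted p = 0.0382, adjusted p = 0.26 with an estimated correlation), but not without F08 (0.289) or F09 (0.0655), with array weights (0.218) or with the mean of a gene's probe sets (0.275). These 2 lists were also the 2 that fry called in the 7 arrays, at an adjusted p of 0.0403 and 0.000429. Since F04 and F05 were left out for their clock genes, none of these calls of clock lists or their members in the 7 arrays is independent evidence. The 10 clock kinases and ubiquitin ligases were not called (adjusted p = 0.535).

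Outside the clock, no gene at its brightest probe set passed in the 7 arrays. That depends on the setting, since 16445 probe sets passed without F08 and 15448 with array weights. Of these, 81.1% and 77.5% lay below the median brightness. Above the upper quartile of brightness, where fewer probe sets were tested, Cytl1, Ephx1, Fkbp5, Fmo2, Inmt, Tspan4 and Unc119 passed. Adamts4 passed after centring and above the median brightness. Unc119 and Chrdl1 passed without a variance trend, and Chrdl1 and Tatdn1 in the F-test of the design text. No gene outside the clock passed after quantile normalization or without F01, F07, F09 or F10. Under the fixed test, the genes outside the clock with the smallest p follow. Among the higher they were Adamts4, a protease of proteoglycans (0.90, adjusted p = 0.0858), Unc119 (1.42, adjusted p = 0.111) and Gm26553 (0.14, adjusted p = 0.121). Among the lower they were Inmt, a methyltransferase of indole amines (-3.47 ± 0.35, SE), Tspan4 (-2.35), Vnn3 (-1.79) and Ephx1, an epoxide hydrolase (-1.70), with adjusted p from 0.111 to 0.116. Adamts4 read 3.01 in BMAL+/+, Vnn3 3.17 in BMAL-/- and Gm26553 2.50 and 2.65, near the floor, where the size of a difference is not resolved. At an unadjusted p under 0.05 there were 10680 probe sets, 9012 higher and 1668 lower, and above the median brightness 1593 were higher and 1627 lower. Quantile normalization gave 3480 higher and 2161 lower, and centring on 1 median gave 2155 and 2052. The count of 10680 went to 2495 without F03, 2734 without F02, 4106 without F09, 4450 without F10, 4612 without F07, 4849 without F01 and 21212 without F08. It was 21298 (18203 higher and 3095 lower) with array weights and 6516 without a variance trend. The groups did not overlap at 7878 probe sets (17.5%), 6711 higher and 1167 lower, where chance gives 5.71%. F04 and F05 were left out for their clock genes, and 89.0% of probe sets below the median brightness were higher in BMAL-/-. The excess over chance therefore does not by itself show an effect of genotype.

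Genes of the vessel wall were lower as sets in camera under both groupings of the arrays. All 17 lists called as labelled were lower, as were 15 of the 16 called without F04 and F05. This direction was therefore not particular to the vessel wall. Over the 100 splits drawn of the 9 arrays, the median was 11 lists called, so a camera call alone does not separate genotype from a random split. An exact permutation test of a list's mean per array called none of the 31 lists. Its exact permutation p, adjusted over the lists, was at least 0.62 as labelled and at least 0.177 without F04 and F05. The 7 arrays have only 35 splits, so the unadjusted exact permutation p there cannot fall below 0.0286. The E-box clock, positive arm, glucocorticoid, antioxidant and fibroblast lists reached that value. With so coarse a test, the lack of calls in the 7 arrays is not evidence against a shift. As labelled, the unadjusted exact permutation p was 0.254 for smooth muscle, 0.0476 for endothelial, 0.23 for vascular tone and 0.548 for matrix genes. Without F04 and F05 the unadjusted exact permutation p was 0.0571 for each but matrix (0.457). The 16 smooth muscle contractile genes had a median difference of -0.46 as labelled (camera adjusted p = 9.3e-05, adjusted p = 0.455 with an estimated correlation) and -0.78 without F04 and F05 (adjusted p = 1.9e-07, 0.303 as an adjusted p with an estimated correlation). In the 7 arrays, Myh11, the heavy chain of smooth muscle myosin, read 13.13 ± 0.13 (SD, n = 4) and 12.00 ± 0.68 (SD, n = 3), and the differences of Myl9, Tagln and Smtn were -1.27, -1.26 and -1.23. None of the 16 passed adjusted over the list alone. Acta2, the most abundant actin of smooth muscle, differed by -0.14. The mean of the list was 9.39 on F02 and 9.57 on F03, the arrays with the highest floor, and 10.3 on F08, within the 10.28 to 10.93 of the BMAL+/+ arrays F01, F07, F09 and F10. The list was still called as labelled without F02 (adjusted p = 0.00768) and without F03 (0.00483), and not with array weights (0.0718). The other probe set of Myh11 had a difference of the opposite sign. As labelled, no gene of any list passed adjusted over its list alone. All such passes given below are therefore from the 7 arrays, a comparison chosen after the clock genes were seen. There, 23.7% of all probe sets had an unadjusted limma p under 0.05. The adjustment within a list does not correct for the number of lists. Under the fixed test, none of these genes passed over all genes.

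The 15 endothelial markers were lower as a set (adjusted p = 0.000851 as labelled and 0.00149 in the 7 arrays, adjusted p = 0.203 and 0.144 with an estimated correlation). Pecam1, a junction protein of endothelium, read 7.63 ± 0.39 (SD, n = 4) and 5.69 ± 0.52 (SD, n = 3) in the 7 arrays and was the only one to pass adjusted over the list alone. Tie1 (-0.97, with BMAL-/- near the floor at 3.34) and Esam (-0.47) were lower without passing, whereas Kdr (0.98) and Cdh5 (0.49) were higher without passing. The endothelial list was not called as labelled after centring (adjusted p = 0.115) or with array weights (0.0718), nor in the 7 arrays after quantile normalization (0.0781), after centring (0.131) or among genes above the median brightness (0.0851). The 22 measured genes of vascular tone and the renin-angiotensin system were lower as a set (adjusted p = 0.000851 and 7.7e-06, adjusted p = 0.284 and 0.144 with an estimated correlation). Ptgs2 (-1.94), which makes prostaglandin precursors, Ace (-1.13), which makes angiotensin II, and Ptgis (-0.83), the prostacyclin synthase, passed adjusted over the list alone in the 7 arrays, and Edn1 (-0.60) did not. Ptgs2 read 2.97 in BMAL-/-, near the floor, so the size of its difference is not resolved, and its other probe set had the opposite sign. With array weights the list was not called as labelled (0.0521). The 22 genes of vascular extracellular matrix had medians of only -0.07 and -0.08, with 13 lower and 9 higher under both groupings (adjusted p = 0.00571 and 0.00188, adjusted p = 0.579 and 0.613 with an estimated correlation). In the 7 arrays the proteoglycans Dcn (-1.17) and Vcan (-1.93) passed adjusted over the list alone, Fn1 (-1.02) did not, and Col4a1 (0.70) was on the other side. Of the 8 probe sets of Vcan, 5 had a difference of the opposite sign. The other probe set of Col4a1 likewise had the opposite sign. The matrix list was not called as labelled without F02 (adjusted p = 0.14), F03 (0.238) or F07 (0.0896), nor in the 7 arrays without F07 (0.0636).

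Markers of macrophages and fibroblasts were also lower as sets. For the 15 macrophage and leukocyte markers the median was -0.44 as labelled and -0.84 in the 7 arrays (camera adjusted p = 1.7e-05 and 8.6e-08, adjusted p = 0.426 and 0.26 with an estimated correlation). In the 7 arrays 5 passed adjusted over the list alone, C1qc (-2.58), C1qa (-2.52), Cd14 (-1.80), Cd163 (-1.42) and Mrc1 (-0.95), all of macrophages. The 11 fibroblast and adventitia markers had 3 that passed so, Pi16 (-2.74), Dpt (-1.89) and Gsn (-0.41), with Cd34 at -1.19 (adjusted p = 0.00143 and 9.3e-06, adjusted p = 0.455 and 0.26 with an estimated correlation). The other probe set of Pi16 had the opposite sign, as did 1 of the 6 of Gsn. As labelled, the fibroblast list was not called without F03 (0.0984) or with array weights (0.691). Ifit3 (-1.80) passed among the 12 interferon genes (adjusted p = 0.00143 and 0.000773, adjusted p = 0.455 and 0.402 with an estimated correlation). Vascular inflammation (adjusted p = 0.239 and 0.189) and lymphocyte markers (0.666 and 0.843) were not called, although the former was in the 7 arrays without F02 (0.049).

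Hormone- and stress-responsive genes moved as follows. Of the 12 glucocorticoid-responsive genes (adjusted p = 0.00275 and 7.1e-05, adjusted p = 0.303 and 0.164 with an estimated correlation), Fkbp5 read 8.73 ± 0.30 (SD, n = 4) and 6.22 ± 0.48 (SD, n = 3) in the 7 arrays. With Mt1 (-1.60), Mt2 (-1.18), Tsc22d3 (-1.18) and Zbtb16 (-1.93) it made 5 that passed as lower adjusted over the list alone, and Cdkn1a (1.42) passed as higher. The other probe set of Mt1 had the opposite sign, as did 2 of the 4 probe sets of Tsc22d3 and 1 of the 3 of Fkbp5. The antioxidant and xenobiotic list was lower (adjusted p = 0.00143 and 0.000152, adjusted p = 0.203 and 0.144 with an estimated correlation), with Gsta3 (-2.70), Ephx1 (-1.70) and Gstt1 (-1.70) past the list-alone threshold and Gstm1 (-1.06) not. Among immediate early genes (adjusted p = 0.00121 and 2.97e-06, adjusted p = 0.532 and 0.349 with an estimated correlation), Ier3 (-1.16) passed and Atf3 (-1.17), Btg2 (-1.11) and Zfp36 (-1.11) did not. For heat shock and chaperone genes (adjusted p = 0.00696 and 8.6e-05, adjusted p = 0.561 and 0.381 with an estimated correlation), Hspa1b (-2.21), Hspa1a (-1.97) and Bag3 (-1.70) were lower and Hspe1 (0.40) higher, none past the list-alone threshold. The other probe set of Hspe1 had the opposite sign. As labelled, the immediate early list was not called without F03 (0.11), nor the heat shock list without F02 (0.112) or F07 (0.116). Also as labelled, the antioxidant list was not called with array weights (0.0989) or among genes above the median brightness (0.122). After quantile normalization the antioxidant (0.0959), glucocorticoid (0.0623) and heat shock (0.267) lists were not called as labelled.

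Of the metabolic lists, white adipocyte genes were called (adjusted p = 0.00143 and 0.0058, adjusted p = 0.455 and 0.566 with an estimated correlation) with medians of -0.12 and -0.09. Cidec, of the fat droplet, was at -1.92, Car3 at -0.40, Lpl at -0.39 and Acly at 0.75 in the 7 arrays. Of the 6 probe sets of Acly, 1 had the opposite sign. That list was not called without F02 (0.0749 as labelled and 0.204 in the 7 arrays), nor in the 7 arrays without F09 (0.116). Fasting and PPAR-responsive genes were called as labelled (adjusted p = 0.0429, adjusted p = 0.336 with an estimated correlation) and not in the 7 arrays (0.235), nor as labelled without F02 (0.079), F04 (0.17), F05 (0.105) or F09 (0.133). Brown adipocyte genes (0.362 and 0.535), oxidative phosphorylation (0.34 and 0.843), glycolysis (0.164 and 0.843), clotting and fibrinolysis (0.132 and 0.0526), cell cycle (0.664 and 0.979), and cell cycle inhibitors and DNA damage response (0.581 and 0.66) were not called. In the 7 arrays Gas6 (-1.38) and F13a1 (-1.16) of the clotting list passed adjusted over the list alone. Some of these lists were called as labelled under another setting. Glycolysis was called as lower without F03 (0.0201) or F07 (0.0434), with the mean of a gene's probe sets (0.0102), with array weights (0.028) and with F01 in BMAL-/- (0.0473), the clotting list without F05 (0.0038) or F09 (0.0233), and oxidative phosphorylation without F08 (0.0246), and cell cycle as higher without F10 (0.028). In the 7 arrays the clotting list was called without F08 (0.0362), F09 (0.01) or F10 (0.0448) and with array weights (0.0112).

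**Figure D2:**
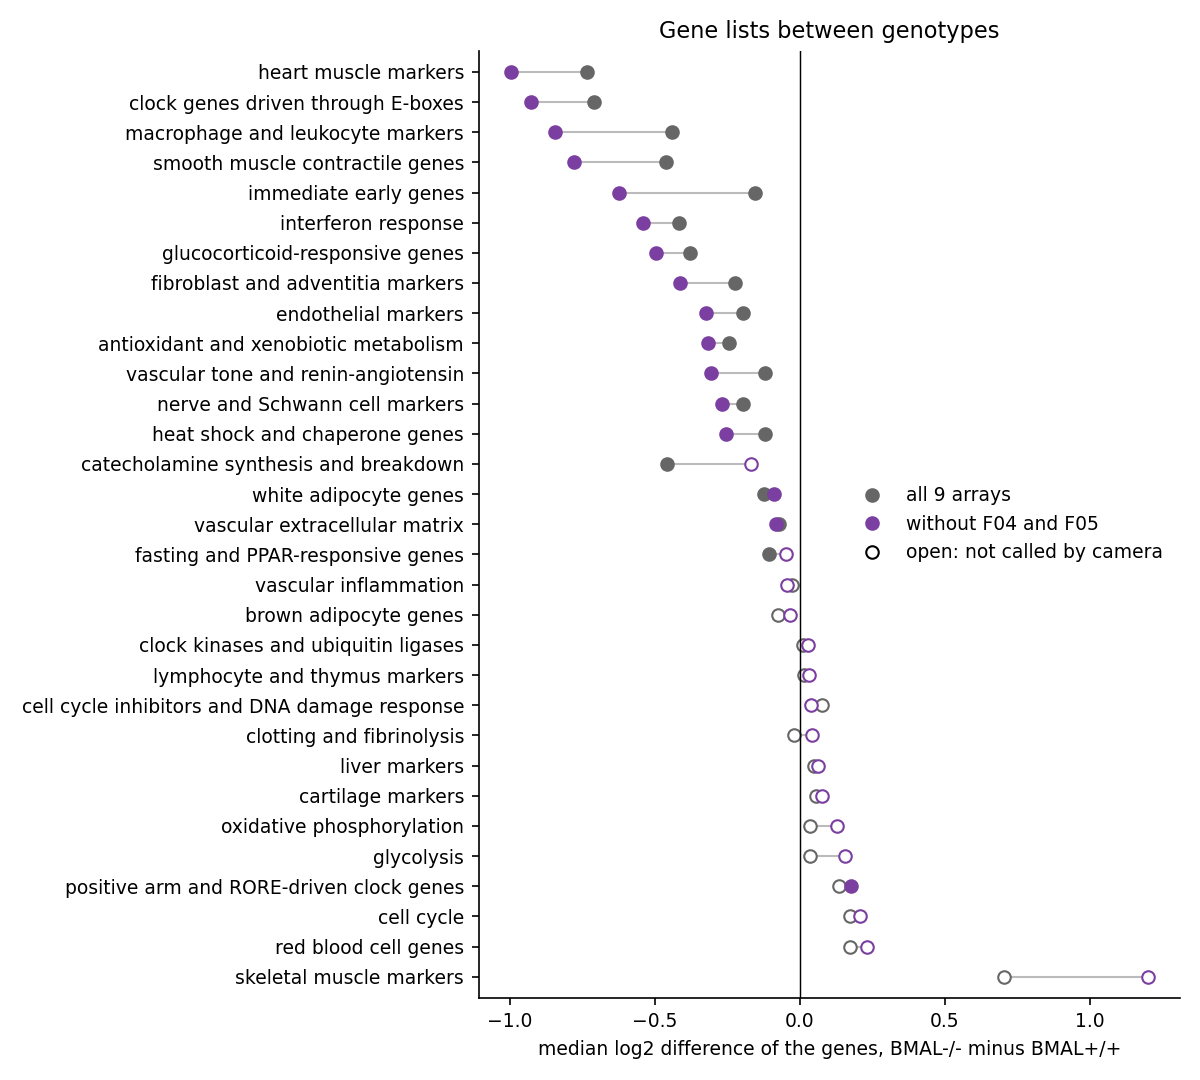
Median log2 difference, BMAL-/- minus BMAL+/+ as labelled (horizontal axis), of the measured genes of 31 lists (vertical axis), for all 9 arrays (grey) and without F04 and F05 (purple). Filled points are lists called by camera, 17 with 9 arrays and 16 without F04 and F05, none of them called with an estimated correlation.

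Transcripts of other tissues varied widely between arrays. The mean of the 14 skeletal muscle markers ran from 4.36 on the array labelled BMAL+/+ F01 to 10.8 on BMAL+/+ F07, and the actin of skeletal muscle, Acta1, read 10.5 ± 3.03 (SD, n = 5) and 11.2 ± 1.71 (SD, n = 4). That list was not called (adjusted p = 0.582 and 0.843), and its median of 0.70 has the opposite sign to its test, as does its median in the 7 arrays. It was called as lower without F01 (0.0071 and 0.0133), with array weights (1.2e-07 and 0.0191) and, as labelled, with F01 in BMAL-/- (3.0e-05). Heart muscle markers ran from 5.14 on F02 to 8.81 on F07 and were called as lower (adjusted p = 0.0429 and 0.00938, adjusted p = 0.579 and 0.566 with an estimated correlation), with Myl7 at -4.17 ± 1.47 (SE), Nppa at -2.21 (BMAL-/- near the floor at 3.41) and Myh6 at -0.58 in the 7 arrays, and Myl3 at 2.01. Catecholamine genes, led by Th and Dbh, ran from 5.53 on F05 to 9.31 on F09, and were called as labelled (adjusted p = 0.0429, adjusted p = 0.579 with an estimated correlation) and not in the 7 arrays (0.162), where they were called without F03 (0.0129) or F10 (0.0192). Nerve and Schwann cell markers ran from 5.02 on F04 to 7.89 on F09 (adjusted p = 0.0159 and 0.0176, adjusted p = 0.561 and 0.566 with an estimated correlation), with Cdh19 at -1.64 and Pmp22 at -0.96. Without F02 neither the heart list (0.428 as labelled and 0.166 in the 7 arrays) nor the nerve list (0.109 and 0.15) was called. The heart list was not called without F07 either (0.259 and 0.0677), nor as labelled without F05 (0.0777) or F09 (0.169), and the nerve list not without F09 (0.33 and 0.183), nor as labelled without F05 (0.086). The catecholamine list was not called as labelled without F09 (0.553), F05 (0.311), F02 (0.101), F08 (0.0698), F07 (0.0536) or F01 (0.0508). The fat markers were high throughout: Ucp1, the uncoupling protein of brown fat, read 13.8 ± 0.62 (SD, n = 5) and 13.6 ± 0.51 (SD, n = 4), and Adipoq 12.98 ± 0.66 (SD, n = 5) and 12.6 ± 0.37 (SD, n = 4). Hba-a1 was near the floor, at 3.15 and 3.27. Red blood cell (0.587 and 0.428), liver (0.164 and 0.189) and cartilage (0.194 and 0.308) lists were not called.

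**Figure D3:**
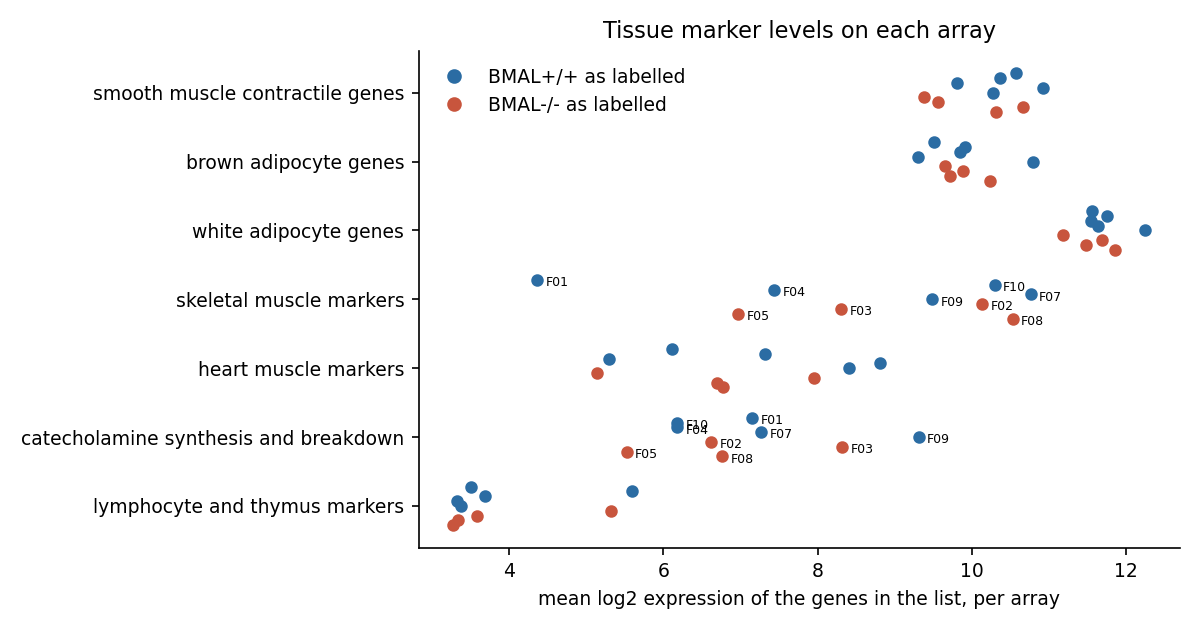
Mean log2 expression per array (horizontal axis) of the genes in 7 lists of tissue markers (vertical axis), coloured by genotype as labelled. Skeletal muscle markers range from 4.36 on F01 to 10.8 on F07, both labelled BMAL+/+, and within BMAL-/- from 6.97 on F05 to 10.5 on F08.

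Probe sets near the floor were shifted in 1 direction. Below the median brightness, 87.5% of probe sets were higher in BMAL-/- as labelled, against 50.03% above it, and the mean over the dim ones was 2.58 on F02 and 2.57 on F03 against 2.48 to 2.53 on the 7 other arrays. Camera compares a list with all other genes, dim ones included. With genes above the median brightness alone, 8 of the 17 lists called as labelled were called (E-box clock genes, smooth muscle, endothelial, vascular tone, fibroblast, macrophage, interferon and immediate early genes), and 11 of the 16 in the 7 arrays, where the matrix, endothelial, white adipocyte, heart and nerve lists were lost. Centring the arrays on 1 median left 4 of the 17 (E-box clock genes, smooth muscle, vascular tone and macrophage), and among the 13 lost were the endothelial, fibroblast, interferon, immediate early and white adipocyte lists (each at 0.115), the glucocorticoid and antioxidant lists (each at 0.189), heat shock (0.321) and matrix (0.356). In the 7 arrays it left 9 of the 16, without the matrix, endothelial, white adipocyte, antioxidant, interferon, heart and nerve lists. With array weights 9 of the 17 were lost, E-box clock genes and smooth muscle among them. Leaving out F02 left 10 as labelled. Of the 128 named genes, 62 had several probe sets, and for 26 of these another probe set had the opposite sign in the 7 arrays.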

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

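The tests of the arrays F04 and F05, and the 80% asked of an exchange, were chosen after their clock genes had been seen. Among the 128 named genes, a single array stood apart from the rest of its group as labelled in 32 of 256 groups of values. Chance gives about 12.8 for genes picked at random. The array labelled BMAL+/+ F04 accounted for 16 of these and the array labelled BMAL-/- F05 for 7, but many of the genes were picked for a small p without these arrays, which makes both stand apart by selection. Over the 426 measured genes of the fixed lists, not picked on a p, a single array stood apart in 123 of 852 groups (chance about 42.6), F04 in 23, F02 in 21, F09 in 19, F10 in 18 and F05 in 7, so these counts are no evidence on F04 and F05. The measure is the gap to the nearest other array as a share of the group's range.

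For F04 in BMAL+/+ the share was 0.978 at Arntl, 0.993 at Npas2, 0.987 at Adamts4 and 0.749 at Clock, where F04 read higher than its group, and likewise 0.794 at Ccdc7a. It was 0.78 at Nr1d2, 0.714 at Per3, 0.791 at Hlf, 0.773 at Fkbp5, 0.759 at Inmt, 0.907 at Tspan4, 0.799 at Ephx1, 0.712 at Vnn3, 0.742 at Myh11, 0.735 at Dcn and 0.784 at Car3, where F04 read lower. For F05 in BMAL-/- it was 0.901 at Arntl, 0.879 at Npas2, 0.954 at Unc119 and 0.847 at Gm26553, where F05 read lower, and 0.867 at Nr1d2, 0.969 at Ptgs2 and 0.873 at Gsta3, where it read higher. Of the remaining 9, F09 read higher at Acadm (0.759), Maoa (0.731) and Narf (0.758), F03 read lower at Bst2 (1, since the 3 other arrays held the identical value of 4.23) and Icam2 (0.837) and higher at Th (0.901), F01 read higher at Ciart (0.941), F10 higher at E2f8 (0.817) and F02 lower at Cry2 (0.919).

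An exchange of the samples or labels F04 and F05 is a candidate explanation. It was tested on 200 bright probe sets outside the clock lists, picked on the 7 other arrays alone. F04 lay nearer the BMAL-/- mean at 84% of them and F05 nearer the BMAL+/+ mean at 93.5%, and both did at 78.5%, just under the 80% set for the explanation, so the test leaves it open. This was the highest share of the 20 pairs of 1 array from each group, and the next was 69% for F04 with F08. Every other pair leaves F04, F05 or both among the arrays that define the groups, so its share is not a like benchmark. A different clock phase, with the genotypes as labelled, also stays open for F04. The 200 probe sets (84% for F04) may themselves be rhythmic, and no genotype marker independent of the clock was tested. For F05 it would need a working clock in an animal labelled as without a working copy of Arntl. The mean of the 15 E-box clock genes was 7.07 on F05, against 5.43, 5.93 and 5.58 on F02, F03 and F08. These values argue against a different phase for F05, a single array.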

How the results depend on the processing

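The comparison without F04 and F05 was chosen after their clock genes were seen, as were its own alternatives, and the test of splits for the count of 0 was chosen after that count. With the arrays as labelled, 0 probe sets passed under each alternative fixed before the data were examined, F01 in BMAL-/- and each array left out included (0 to 0), and 4 passed without arrays F04 and F05. The Arntl difference of 1.67 stayed above 0 and short of the threshold (1.34 to 2.49 with an array left out, 0.388 with array weights and 0.981 with F01 in BMAL-/-), and was at least 3.27, with BMAL+/+ near the floor, and past it without F04 and F05. Over its 20 alternatives the adjusted p ran from 0.000511 to 0.812. Of 17 lists called as labelled, quantile normalization left 9, centring the arrays on 1 median 4, array weights called 10, genes above the median brightness 8, and an estimated correlation and fry 0 each, and leaving out an array gave 10 (without F02) to 18. Without F04 and F05, the 4 probe sets became 2 after quantile normalization, 9 above the upper quartile of brightness and 15448 with array weights, and 2 (without F01, F07 or F10) to 16445 (without F08) with an array left out. Of the 15448, 77.5% lay below the median brightness, and of the 16445, 81.1%. The 16 lists became 9 after centring, 0 with an estimated correlation and 2 with fry, and 14 to 18 with an array left out. The cause was not tested, except that filters test fewer probe sets. No called result reversed, while named genes that did not pass changed sign in 59 results as labelled and 39 without F04 and F05. Of the named genes without F04 and F05, 149 results came past the threshold, 70 each with array weights and without F08, and 7 (all Nr1d2) fell short of it. No level near the floor can be ordered, since these values have no signal over background to resolve.

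With F04 and F05 left out, 1 of 35 splits gave as many as 4 probe sets (highest other split 2), which decides nothing, since the arrays were left out for their clock genes and 3 of the 4 are clock genes. At an unadjusted p under 0.05, 1 of 35 splits, the labelled one, gave as many as 10680 (median 962, highest other 9347). This does not test genotype either, since the same 2 arrays were left out for lying with the other genotype. For lists, 5 of 35 splits gave as many as 16 (median 11, highest other 18), so a random split is not excluded. As labelled, all 100 of 100 splits drawn gave at least 0 probe sets (highest other 13497), as any split must. Of the 100, 13 gave as many as 3903 at an unadjusted p under 0.05 (median 760, highest other 20374) and 7 as many as 17 lists (median 11, highest other 18). Neither of the last 2 excludes a random split. The split with 13497 set F02, F03, F04 and F05 against the rest, a structure of the arrays other than the labels. Of its probe sets 80.4% lay below the median brightness, and these arrays had the highest means over the dim probe sets (2.52 to 2.58).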

Other observations

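All tests in this part, with their limits, were chosen after the patterns had been seen. The levels of other tissues give a picture of what the dissections held. Lymphocyte and thymus markers ran from 3.27 on F08 to 5.60 on F10, and brown adipocyte genes from 9.30 on F07 to 10.8 on F09. Xist read at most 2.86 on any array, near the floor, as in male mice.

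Skeletal muscle taken with the aorta in part of the dissections is a candidate source of the muscle markers. The same pair of arrays, F07 and F08, was the highest for 10 of 14 markers (71.4%), under the 80% set for this explanation, so it stays open. Chance gives 2.78% for a pair named in advance. This pair was picked as the commonest and the markers had an estimated correlation of 0.82, so 2.78% is no benchmark here. Without F04 and F05 the marker means overlapped (8.31 to 10.5 in BMAL-/-, 4.36 to 10.8 in BMAL+/+, exact permutation p = 0.857). With the labels as given, genotype alone does not account for the spread within BMAL+/+. With so few arrays and so wide a spread, the overlap cannot exclude an effect of genotype, which stays open.

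Dim probe sets that were higher in BMAL-/- may come from the background correction or scaling of single arrays. F08 had a mean of 2.50 over them, within the 2.48 to 2.52 of the BMAL+/+ arrays other than F04, while 2 of the arrays F02, F03 and F08 lay above every BMAL+/+ array. F08 is a single array, so neither this nor genotype as the cause is excluded, and both stay open.

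The mice were partly backcrossed, so a stretch of founder-strain chromosome around Arntl may differ between the genotypes. This was tested without F04 and F05 as the share of bright genes at an unadjusted p under 0.05 near Arntl, against 14.7% of all bright genes, at 4 widths. It was 35% for the 10 nearest genes on each side, a share that 1.94% of windows elsewhere matched, 24% for 25 (5.74% of windows), 15% for 50 (49.3%) and 16% for 100 (34.1%). The result depends on the width and does not settle the hypothesis.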
